A study of Mus musculus with 2 samples.

How the data were processed

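Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open chromatin. The tissue was neural tube of mouse embryos at 14.5 days of development. Per the labels, the tissue came from embryos of mixed sex of the strain B6NTac;B6NCrl/Lap. Replicate 1 pooled tissue of 17 embryos and replicate 2 pooled tissue of 34 embryos. The labels number them as separate biological replicates. There was 1 group, so no comparison between conditions and no test between groups could be made. The data used here were 12 peak lists, 3 per replicate and 6 made from both replicates.

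Per the notes deposited with the samples, all lists were on the mouse build mm10 (GRCm38). The aligner, the peak caller, their versions and any shift of read ends for the transposase were not given in the sources used here. Each replicate had a pseudoreplicated list, a list ranked by the irreproducible discovery rate (IDR) and a list thresholded on it. The pooled data had a pseudoreplicated list, a replicated list, 2 ranked lists and 2 thresholded lists, called optimal and conservative here. Per the same deposited notes, every list except the ranked ones was made from the alignments and a further file whose kind was not stated. The deposited signal value of each peak was a ratio above 1, read here as fold enrichment over the caller's background. How the authors computed that background was not given in the sources used here. Significance was given by the authors as −log10 p and −log10 q of each summit. The score in the IDR lists was the authors' IDR score, and the ranked lists held the deposited −log10 of the global IDR as a further score. In the other lists the deposited score followed −log10 p. The fold and the significance of each peak are the authors' values, used here to describe, rank and filter peaks. Peak lists hold no read totals, so the depth of each replicate is unknown.

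Rows of a list that overlapped were merged into regions, each taking the summit of its row with the highest −log10 p. The fold, the −log10 p and the −log10 q of a region were each the highest among its rows. The fold of a region could thus come from another row than its summit. Only the assembled chromosomes were used. Regions counted as shared when they overlapped by at least 1 bp. Coordinates are counted from 1. Genes came from the basic set of GENCODE M21, with 21851 protein-coding genes. A region was assigned to promoters when its summit lay within 1 kb of a transcription start site (TSS) of a protein-coding gene, and otherwise to exons, introns or intergenic sequence. A gene had a promoter region when any region overlapped the window of 1 kb around one of its TSSs. Distal regions had summits over 1 kb from any TSS, coding or not, and belonged to the gene of the nearest protein-coding TSS within 100 kb. Gene results and motif results used the replicated list. Shares carry 95% Wilson intervals, and motif ratios carry 95% Poisson intervals. Both cover counting error only, not differences between embryos. Values from the separate replicates are given as mean ± SD with n = 2.

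Gene lists, motif consensus sequences, the rule for named genes and the main definitions were set before the data were examined. There were 19 gene lists with 355 different genes. Sox10, Foxd3 and Sox17 each belonged to 2 lists. The lists covered neural progenitors and radial glia, dorsoventral progenitor domains, spinal interneuron transcription factors, motor neurons, pan-neuronal genes, glial genes, forebrain and midbrain transcription factors, Hox genes, and neural crest with sensory neurons. Other lists covered skeletal muscle, mesenchyme with cartilage and bone, erythroid cells, endothelium with pericytes, leukocytes, hepatocytes, cardiomyocytes, epithelium, gut and housekeeping genes. Each list's count was ranked among 10000 random lists of the same size. The random lists were matched on deciles of the CpG observed over expected ratio for promoters, and on deciles of the length of the distal domain for distal regions. The resulting percentile describes these libraries and is not a p-value. A percentile of at least 97.5 or at most 2.5 is called high or low in the text. That boundary, and the contrast of 6 neural lists with 9 lists of other tissues and with random genes matched in the same way, were not among the choices made beforehand. On simulated data with 200 changed genes, lists of 20 genes with 1 extra distal region per gene reached the 97.5 percentile in 6 of 10 cases. With 2 or 3 extra regions they reached it in 10 of 10 cases, and unchanged lists did so in 1 to 2 of 100. Lists of 20 genes whose promoter regions had been removed fell to the 2.5 percentile or lower in 10 of 10 cases, and unchanged lists in 2 of 100. As every promoter region was removed, the outcome of the changed lists was fixed in advance, and partial deficits were not simulated.

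For 30 consensus sequences, sites per kb on both strands in the central 100 bp at summits were divided by those 200 to 400 bp away on either side. The same ratio was taken for up to 20 shuffles of the letters of each consensus. A motif is called enriched where the lower bound of its interval was above 1 and its ratio exceeded that of every shuffle, a criterion that was not among the choices made beforehand. Site counting, overlap and TSS assignment were tested on simulated data. Strong distal regions were aligned to the mitochondrial genome and to the whole genome with BLAST 2.17.0 at an e-value of 1e-05. An alignment to the mitochondrial genome was counted at 80% identity or more over at least 50% of a region, and another match in the genome at 95% identity or more.

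The text names, within each list, up to 4 members with most distal regions and members with no promoter region. It also names the 25 genes with most distal regions genome-wide and the 10 distal and 10 promoter regions of highest mean fold. The 5 promoter regions of highest fold called in a single replicate, taken by gene, are named too. Any Hox gene, any motif and any of at most 5 exceptions in a statement about a list could be named. Alternatives covered stricter peak lists, −log10 q of at least 5, reciprocal overlap of 50%, equal numbers of top-ranked regions, promoter windows of 500 bp and 2 kb, distal limits of 50 kb and 500 kb, unmatched random lists, wider motif windows, and each replicate's own list. Signal tracks and alignments were not analysed here. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.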

Results

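Open chromatin of the mouse neural tube at embryonic day 14.5 was mapped in 2 replicates, each a pool of neural tube tissue. The replicate descriptions name the tissue as neural tube and do not say which parts of it were taken. The neural tube gives rise to the brain and the spinal cord, and at this age it holds dividing progenitors, young neurons and early glial cells. The design asks how well the pools match and which parts of the genome are accessible in this tissue. The lists hold no read totals, so depth could not be compared between the replicates.

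Replicate 1 had 72016 accessible regions covering 43.8 Mb, and replicate 2 had 37968 regions covering 24.5 Mb, a ratio of 1.90 in number. Nearly all regions of the smaller set were also in the larger one. Of the regions of replicate 2, 92.0% (95% Wilson interval 91.7 to 92.2%) overlapped a region of replicate 1, whereas 46.5% (46.2 to 46.9%) of the regions of replicate 1 overlapped one of replicate 2. Across the 33504 regions of replicate 1 with a partner, the fold enrichment of both replicates had a Spearman correlation of 0.823 and a Pearson correlation of 0.838 on the log2 scale. These correlations run across regions, which are not independent replicates.

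Regions called in replicate 1 alone numbered 38512, and those called in replicate 2 alone numbered 3045. Promoters made up 5.12% of the former and 8.47% of the latter, against 38.6% and 38.9% of the shared regions of each replicate. Median fold was 3.31 in regions of replicate 1 alone and 6.19 in its shared regions, and 3.16 against 4.69 in replicate 2. Among genes with a promoter region in the list of a single replicate, the 5 of highest fold all had it in replicate 1. They were Zkscan7 (fold 13.9), Slc4a2 (11.7), Trim12c (11.1), Magix (9.72) and Fam198a (9.54). This selection is by gene, so such a region may still overlap one of replicate 2 that does not reach the gene's promoter window. Slc4a2 encodes an anion exchanger, and Zkscan7 encodes a zinc finger protein. Given the same number of top-ranked regions from each replicate, the shared parts were 74.9% and 79.5%, and 9534 and 7768 regions were called in a single replicate. By decile of −log10 p in replicate 1, a division chosen after the results were seen, 100% of regions in decile 1 were found in replicate 2, at promoters and elsewhere, and 17.2% and 6.10% in decile 10.

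**Figure D1:**
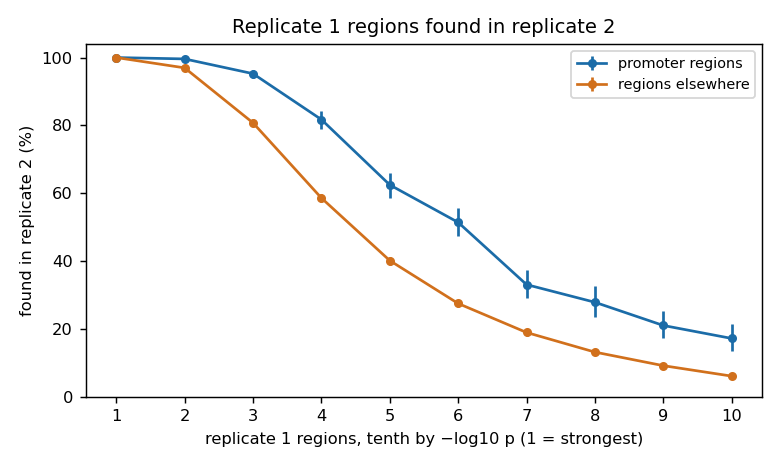
Share of replicate 1 regions found in replicate 2 (percent, vertical axis, with 95% Wilson intervals) by decile of −log10 p in replicate 1, with 1 the strongest, at promoters and elsewhere. Both start at 100% and end at 17.2% and 6.10%.

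The replicated list held 59986 regions over 43.0 Mb, with a median width of 608 bp and a median fold of 4.15. Of the 72992 regions of the pooled pseudoreplicated list, 74.8% overlapped the replicated list, 39.2% the optimal IDR list of 28644 regions and 31.5% the conservative IDR list of 23024 regions. Of the replicated regions, 82.8% overlapped a region of replicate 1's own list and 57.3% one of replicate 2's own list. A replicated region was therefore not always called in each replicate's own list. Of the conservative regions, 99.9% lay in the replicated list and 96.7% overlapped a region of replicate 2, the smaller of the single-replicate sets.

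Promoters were the most overrepresented class of accessible sequence. They held 24.3% of replicated summits (23.9 to 24.6%), 11.9-fold above their 2.03% share of the genome. Introns held 39.2% (0.955-fold), intergenic sequence 32.0% (0.599-fold) and exons outside promoters 4.55% (1.30-fold). Promoter regions were also stronger and wider, with a median fold of 8.13 and a median width of 1166 bp, against a fold of 3.56 in introns and 3.92 between genes. The promoter share depended on the list, at 20.7% in replicate 1, 36.4% in replicate 2 and 50.3% in the conservative list.

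**Figure D2:**
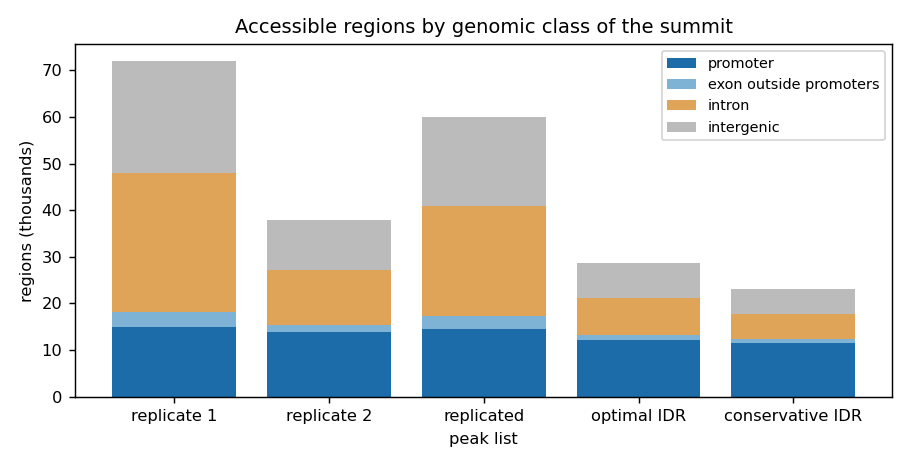
Number of accessible regions (vertical axis, in units of 1000) in 5 peak lists, stacked by the genomic class of the summit. Promoter regions numbered 14555 in the replicated list and 11589 in the conservative list, while intron regions numbered 23526 and 5355.

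A promoter region was present at 13922 of 21851 protein-coding genes (63.7%). In the replicates' own lists, 13069 genes had one in both, 960 in replicate 1 alone and 53 in replicate 2 alone. The strongest promoter regions were led by Iars, which encodes isoleucyl-tRNA synthetase, at 13:49681698-49682720 with a fold of 23.4 ± 4.12 (SD, n = 2). Tmem218 at 9:37207599-37208624 followed (22.9 ± 3.34), then the helicase-like gene Hltf at 3:20057379-20058463 (22.8 ± 2.64) and Depdc1a at 3:159494762-159495854 (22.6 ± 5.35). Promoters of Gm49359, Fopnl, Pnpt1, Hsd17b7, 2610008E11Rik and Diaph3 had folds of 21.3 to 22.3. The order of these top 4 differed between replicates, with Depdc1a highest in replicate 1 and Hltf highest in replicate 2.

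Genes of neural cell types had more distal regions than random genes with distal domains of like length, and genes of other tissues did not. The neural group held the progenitor, dorsoventral, interneuron, motor neuron, pan-neuronal and glial lists. Its 122 genes in 6 lists had 5.08 distal regions each against 2.60 in matched random genes (percentile 100), and the 140 genes of 9 lists of other tissues had 1.58 against 1.57 (52.5 percentile). The difference between the groups was 3.50, or 2.48 beyond that of matched genes. In the conservative list the difference was 0.957 and in replicate 2 alone it was 1.84, against 0.229 and 0.511 in matched genes. Most of the difference in promoters was also found in random genes of like CpG content. A promoter region was present at 86.9% of the neural genes and at 40.0% of the others, against 86.4% (58.0 percentile) and 45.4% (2.67 percentile) in matched genes. The difference of 46.9 percentage points compared with 41.0 (95.3 percentile), and this percentile was 87.1 in the conservative list and 97.8 to 99.97 with other promoter windows and in either replicate alone. In the conservative list both groups lay below matched genes, at 63.9% against 78.4% and 17.9% against 36.7% (percentile 0 for each). With the forebrain and midbrain list and the neural crest list added to the neural group, its 158 genes had 4.66 distal regions against 2.54 (percentile 100), and 82.3% had a promoter region against 87.5% (0.625 percentile). The difference in promoters was then 42.3 points against 42.2 in matched genes (50.8 percentile). The matching and the wider group were chosen after seeing the data.

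Among pan-neuronal genes, which encode cytoskeletal, synaptic and RNA-binding proteins shared by most neurons, 20 of 20 had a promoter region (99.4 percentile of random lists). Their median of 6.5 distal regions compared with 2 in random lists (percentile 100), and in replicate 1 alone a median of 4.5 compared with 2.5 (94.7 percentile). The microtubule-associated protein gene Map2 (1:66175273-66442583) had 17 distal regions, as did the neurexin gene Nrxn1 (17:90033631-91093071), a synaptic adhesion gene, and Rbfox3, which encodes the neuronal marker NeuN. The transcription factor gene Myt1l had 13. In the separate lists, Map2 had 23 distal regions in replicate 1 and 8 in replicate 2, and Myt1l had 14 and 13. Promoter fold was 16.9 ± 3.29 at Nrxn1 and 3.38 ± 0.118 at Rbfox3 (SD, n = 2).

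Neural progenitor and radial glia genes had promoter regions at 20 of 20 members (96.6 percentile). They had a median of 4 distal regions against 1.5 in random lists (99.7 percentile). The N-cadherin gene Cdh2 had 19, the receptor gene Notch1 11, and the transcription factor genes Rfx4 and Pax6 10 each. Pax6 (2:105668900-105697364), which patterns progenitors, had a promoter fold of 6.20 ± 0.822, and 11 distal regions in replicate 1 against 5 in replicate 2. The numbers at Cdh2 were 19 and 5, at Notch1 10 and 4, and at Rfx4 13 and 3.

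Genes of the dorsoventral progenitor domains, which are set by Sonic hedgehog from ventral and BMP signals from dorsal sides, had a promoter region at 23 of 26 members (27.9 percentile). They had a median of 4.5 distal regions against 2 (99.98 percentile). The hedgehog effector gene Gli3 had 12, the dorsal genes Pax7 and Pax3 had 11 and 10, and the proneural gene Ascl1 had 8. In replicates 1 and 2 alone the numbers were 17 and 5 at Gli3, 9 and 4 at Pax7, 10 and 6 at Pax3, and 10 and 7 at Ascl1, which led in replicate 2. The members with no promoter region were Nkx2-2, Dbx1 and Dbx2, which mark progenitors of ventral and intermediate domains.

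Spinal interneuron transcription factors combined many distal regions with fewer accessible promoters than CpG-matched genes. Their median was 4 distal regions against 2 (99.8 percentile), led by Pax2 with 13, Lmx1b with 12, Pax8 with 9 and Pou4f1 with 8. Pax2 had 15 in replicate 1 and 4 in replicate 2, Lmx1b 17 and 8, Pax8 10 and 6, and Pou4f1 10 and 3. A promoter region was present at 19 of 25 members against a random median of 23 (0.185 percentile). Sox14, Barhl1, Tlx1, Evx1, Evx2 and Gata2 had none. Against random lists not matched on CpG, the promoter percentile was 89.7.

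Glial genes had a median of 4 distal regions against 1 (percentile 100) and promoter regions at 11 of 18 members (29.1 percentile). The promoter count was 15 with a window of 2 kb (98.8 percentile) and 7 in the conservative list (0.93 percentile). Nfib had 15 distal regions and Nfia 8. Both encode nuclear factor I proteins that act at the onset of gliogenesis. Pdgfra, a receptor gene of oligodendrocyte precursors, and the myelin gene Mbp had 7 each. In replicate 1 Nfib led with 20 against 8 at Nfia, and in replicate 2 Nfia led with 10 against 5 at Nfib, while Pdgfra had 9 and 4 and Mbp 10 and 2. No promoter region was called at Gfap, Aqp4, S100b, Plp1, Mog, Cspg4 or Sox10, among them markers of mature astrocytes and myelinating cells. Motor neuron genes had promoter regions at 13 of 13 members (93.1 percentile; 8 of 13 and 3.6 in the conservative list) and a median of 2 distal regions against 1 (73.8 percentile). Foxp1, which specifies limb-innervating motor neurons, had 13, Lhx4 had 6, and Slc5a7 and Onecut1 had 3 each. Foxp1 had 18 in replicate 1 and 6 in replicate 2. In the conservative list, the distal percentile was 99.5 for glial genes, and between 94.3 and 96.99 for the pan-neuronal, progenitor, dorsoventral and interneuron lists. The dorsoventral promoter percentile was 0 in the conservative list, 0.085 in replicate 2 alone, 2.26 in replicate 1 alone and 99.7 without matching on CpG.

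**Figure D3:**
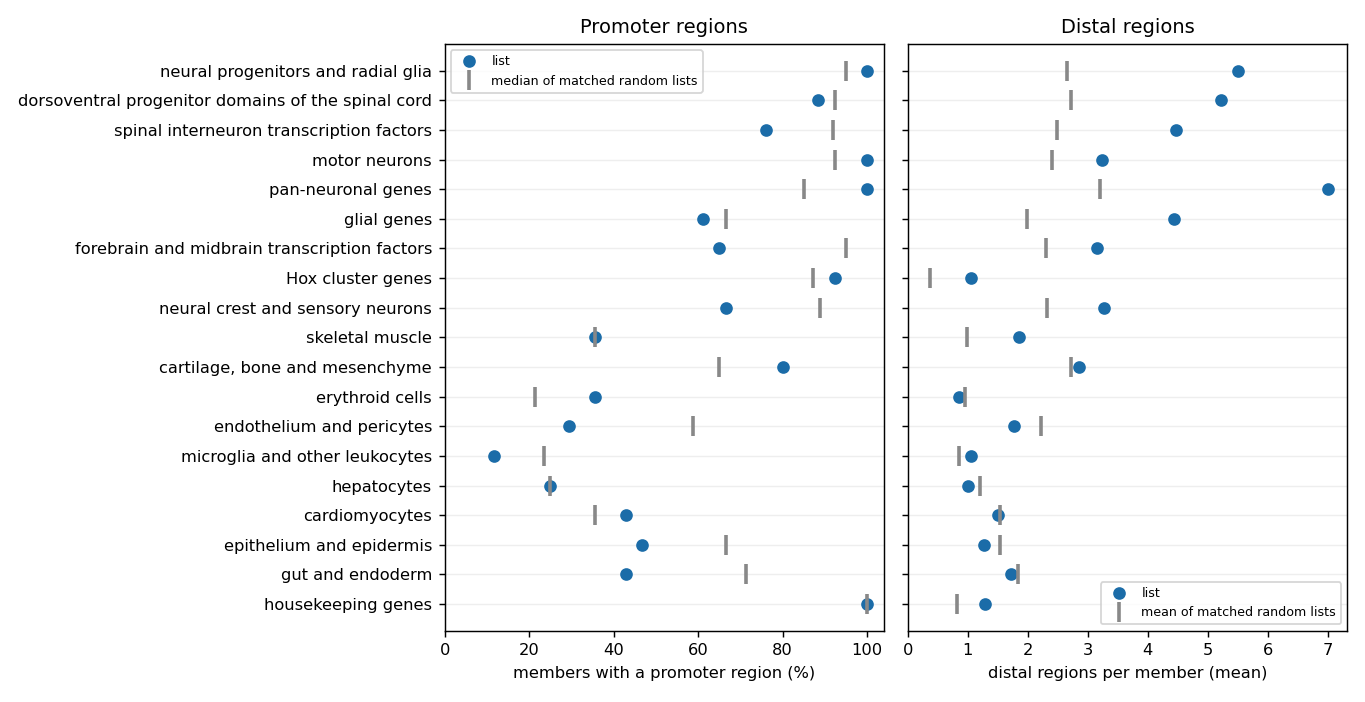
Share of list members with a promoter region (left, percent) and mean number of distal regions per member (right) for the 19 gene lists, as points, with the value of matched random lists as grey ticks. Pan-neuronal genes had a mean of 7 distal regions against 3.21 in random lists, and endothelial genes 1.76 against 2.21.

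Forebrain and midbrain transcription factors had a promoter region at 13 of 20 members against a random median of 19 (percentile 0). None was called at Fezf2, Pax5, Six3, Lhx6, Rax, Six6 or Eomes. Their median was 3 distal regions against 1 (98.0 percentile), with 10 at Otx2, a gene of anterior brain identity, and 6 each at Emx2, Dlx2 and Nkx2-1. Otx2 had 9 in replicate 1 and 3 in replicate 2. The distal percentile was 91.4 for the mean (3.15 against 2.30), and for the median it was 90.8 within 500 kb, 91.8 in the conservative list, and 90.02 and 97.4 in replicates 1 and 2 alone. Neural crest and sensory neuron genes had promoter regions at 12 of 18 members against 16 (0.775 percentile), with none at Phox2b, Runx3, Sox10, Scn10a, Prph or Avil. Their median was 2.5 distal regions against 1 (96.5 percentile). The neurotrophin receptor genes Ntrk3 and Ntrk2 had 11 and 8, and Tfap2b and Phox2a had 7 each. Ntrk3 had 15 in replicate 1 and 3 in replicate 2, where Tfap2b led with 4. With random lists not matched on CpG, the promoter percentiles were 53.2 for the forebrain and midbrain list and 58.6 for the neural crest list, and the latter was 10.9 with a window of 2 kb.

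Genes of other tissues were mostly near or below random lists. Endothelial and pericyte genes had a promoter region at 5 of 17 members against 10 (0.04 percentile) and a median of 1 distal region (47.4 percentile), with 5 each at Pdgfrb and Erg. Gut genes had promoter regions at 6 of 14 members against 10 (0.3 percentile) and a median of 2 distal regions (91.7 percentile), with 8 at Isx. Epithelial genes had promoter regions at 7 of 15 members against 10 (1.7 percentile) and a median of 1 distal region (72.9 percentile), with 4 at Grhl2. Leukocyte genes had promoter regions at 2 of 17 members against 4 (11.4 percentile) and a median of 0 distal regions (44.6 percentile), with 5 at Laptm5 and 3 at Ptprc, the gene of the pan-leukocyte antigen CD45.

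Erythroid genes had promoter regions at 5 of 14 members against 3 (94.2 percentile), with none at the globin genes Hba-a1, Hba-a2, Hbb-bs, Hbb-bt and Hbb-bh1. Their median was 0 distal regions (42.7 percentile), with 7 at Ank1. Their promoter percentile was 98.1 in replicate 2 alone, which is high, 93.1 in replicate 1 alone and 69.3 in the conservative list. Hepatocyte genes had promoter regions at 4 of 16 members against 4 (55.2 percentile) and a median of 1 distal region (86.3 percentile), with 4 at Apob. Cardiomyocyte genes had promoter regions at 6 of 14 members against 5 (70.8 percentile) and a median of 1.5 distal regions (96.4 percentile), with 4 at Myl2. Their promoter count was 3 in the conservative list (13.4 percentile), 3 in replicate 2 alone (6.0 percentile) and 5 in replicate 1 alone (35.2 percentile). Mesenchyme, cartilage and bone genes had promoter regions at 16 of 20 members against 13 (96.4 percentile) and a median of 3 distal regions against 2 (93.5 percentile). The promoter count was 6 of 20 in the conservative list (0.02 percentile) and 9 of 20 in replicate 2 alone (0.86 percentile). Pax1, a gene of the vertebral precursors, had 7 distal regions and Foxc1 had 6. Without matching on CpG, the promoter percentiles were 1.91 for erythroid, 2.01 for muscle, 0.085 for hepatocyte, 0.005 for leukocyte, 9.27 for epithelial and 6.26 for gut genes. By the mean number of distal regions, the percentiles were 51.8 for cardiomyocyte, 60.04 for mesenchyme, 45.3 for gut and 36.6 for hepatocyte genes.

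Skeletal muscle genes were the exception among these tissues. Their median was 2 distal regions against 0 in random lists (99.7 percentile), with 5 at the embryonic myosin gene Myh3, 4 each at Cdh15 and Myog, and 3 at Chrna1. Myh3 had 5 in replicate 1 and 1 in replicate 2. A promoter region was present at 5 of 14 members against 5 (49.97 percentile), and none at Myog, Myf5 or Myh3. The promoter count was 2 in the conservative list (6.1 percentile) and in replicate 2 alone (2.625 percentile). It was 6 in replicate 1 alone (73.8 percentile) and 7 with a window of 2 kb (85.9 percentile). The distal percentile was 49.5 in the conservative list, 90.3 within 50 kb and 93.8 in replicate 2 alone. Housekeeping genes had promoter regions at 18 of 18 members (74.5 percentile) and a median of 1 distal region against 0 (97.7 percentile), with 6 each at Ubc and Ywhaz. Their distal percentile was 89.7 for the mean, and for the median it was 49.99 in the conservative list, 49.5 in replicate 2 alone and 39.8 in replicate 1 alone.

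Genome-wide, none of the 25 genes with most distal regions was in a list set beforehand. Bach2 (4:32238804-32586108), which encodes a transcriptional repressor, led with 36 in a domain of 367 kb. Frmd4a (2:4017717-4614043) had 34, the ankyrin gene Ank3 (10:69398773-70027438), which organises the axon initial segment, 30, and the Notch coactivator gene Maml3 and Nckap5 29 each. Nrxn3 had 28, Ank2 and Nav2 26, Schip1 and Bcor 25, Pde4d 24, Kalrn 23, and Adgrl2, Auts2 and Ncor2 22. Pknox2, Lrrc4 and Apba2 had 21, and Vav3, Fyn, C530008M17Rik, Kcnmb2, Dst, Zfp423 and Lingo1 20. The counts differed between replicates, with 39 in replicate 1 and 11 in replicate 2 at Bach2, and 25 and 19 at Maml3. These raw counts are not corrected for domain length.

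Hox genes, which give cells their position along the body axis, had a promoter region at 36 of 39 members (81.6 percentile), with none at Hoxb8, Hoxb13 or Hoxc6. In the conservative list 19 of 39 had one (percentile 0), and the percentile was 18.0 and 19.5 in replicates 1 and 2 alone. Regions covered all 4 clusters more densely than the genome. The HoxD cluster (2:74663310-74770142) held 26 regions and HoxA (6:52150590-52265880) 25, with a coverage 10.2-fold and 8.05-fold that of the genome. HoxC (15:102916103-103041852) held 16 (6.09-fold) and HoxB (11:96189316-96373256) 26 (4.83-fold). In the replicates' own lists, 9.30% ± 1.55 of HoxA, 5.88% ± 1.87 of HoxB, 8% ± 3.62 of HoxC and 10.4% ± 4.02 of HoxD was covered (SD, n = 2). HoxB had the lowest coverage in each, at 7.20% in replicate 1 and 4.55% in replicate 2. The highest was HoxD in replicate 1 (13.2%) and HoxA in replicate 2 (8.20%).

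Promoter fold was highest at Hoxd1 (8.51 ± 2.71) and Hoxa1 (6.49 ± 0.147), followed by Hoxc10 (5.94 ± 0.00407), Hoxa4 (5.91 ± 1.57) and Hoxd10 (5.67 ± 1.51; SD, n = 2 throughout). Hoxd1 led in each replicate, but the order behind it differed, with Hoxa4 (7.02) next in replicate 1 and Hoxa1 (6.39) in replicate 2. Anterior genes of low paralog number and posterior genes of high number both had promoter regions. Among the latter, Hoxc13 had a fold of 4.80 ± 0.684. Hoxb2, Hoxb3, Hoxa5, Hoxc9, Hoxd12 and Hoxd13 were called in replicate 1 alone, and Hoxb8, Hoxb13, Hoxa11 and Hoxa13 in replicate 2 alone. Hoxc6 and Hoxc12 were in neither replicate's own list. The median of 1 distal region per Hox gene compared with 0 in random lists (percentile 100), with 9 at Hoxc4 and 4 at Hoxd3. This percentile was 50 in the conservative list and in replicate 2 alone.

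**Figure D4:**
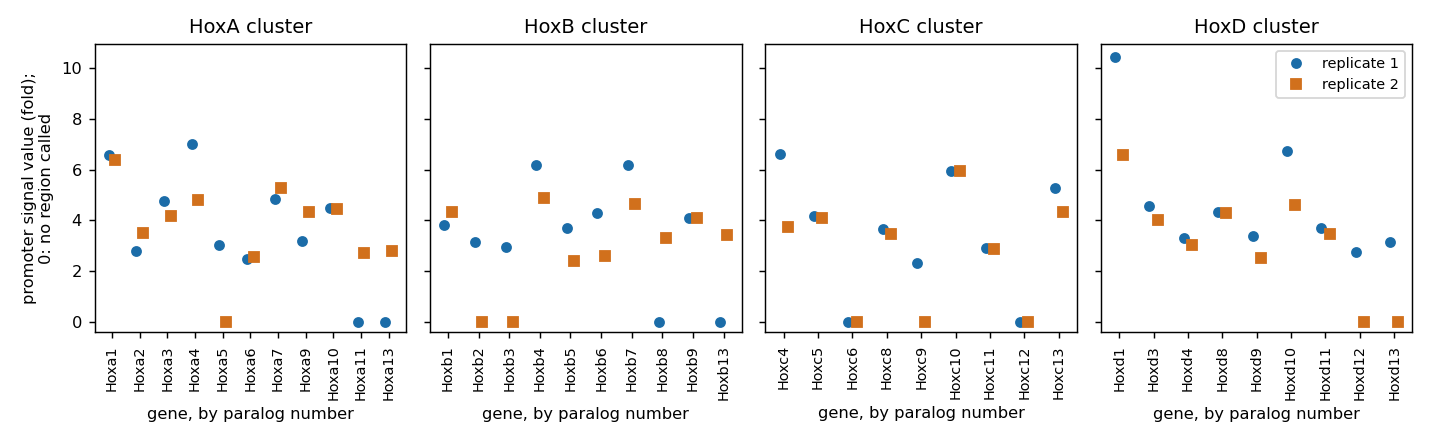
Promoter fold enrichment (vertical axis) of each Hox gene in replicate 1 (circles) and replicate 2 (squares), by cluster and paralog number, where a point at 0 means that no region was called. Hoxd1 had folds of 10.4 and 6.59, and Hoxa1 6.59 and 6.39.

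At the 43072 distal summits, sites of CTCF, RFX, bHLH, POU and SP/KLF factors and the rare full NFI site were enriched over the flanks. RFX, POU and SP/KLF sites lay in the centre of only 0.518%, 0.926% and 0.989% of summits. The bHLH sites CAGCTG and CAGATG lay at 12.6% and 11.9%. The core site of CTCF, the protein of chromatin insulators, was 26.5-fold denser in the central 100 bp than in the flanks (95% Poisson interval 23.4 to 30.1), with a highest ratio of 5.95 among shuffles, and lay at 3.96% of summits. RFX sites, bound by a family that includes Rfx4, were 9.28-fold denser (7.36 to 11.7; shuffles up to 1.82), and full NFI sites 6.49-fold (3.57 to 11.8; shuffles up to 2.88). The NFI value rests on 27 central sites, at 0.0627% of summits, and the shorter NFI site TTGGCA, with 3465 central sites, was not enriched (1.43; shuffles up to 2.05). The E-boxes CAGCTG and CAGATG, bound by proneural bHLH factors, had ratios of 2.41 (2.34 to 2.49; shuffles up to 2.17) and 1.55 (1.503 to 1.60; shuffles up to 1.46). SP/KLF sites had a ratio of 1.962 (7 shuffles, up to 1.67), and the POU octamer 1.28 (1.14 to 1.42; shuffles up to 0.760). In the replicates' own lists, the CTCF ratio was 24.2 ± 0.188, the RFX ratio 9.06 ± 1.56 and the NFI ratio 6.22 ± 2.17 (SD, n = 2). In the conservative list the CTCF ratio was 40.8 and the RFX ratio 22.5 (13.8 to 36.7; shuffles up to 12.8), and with wider windows the RFX ratio was 5.27.

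These 7 of 30 motifs were enriched. SOX sites (1.01), the homeodomain site TAATTA (1.01) and MEF2 sites (1.01) exceeded their shuffles, but their intervals included 1. The median ratios of their shuffles were 0.735, 0.414 and 0.413, so sequences of the same letters were sparser at the centre than in the flanks. ZIC (1.84), NRF1 (7.14) and NFY (1.58) sites did not exceed the highest of their shuffles, at 2.59, 12.6 and 1.59. Their intervals were above 1, at 1.69 to 2.01, 4.11 to 12.4 and 1.504 to 1.66. NFY thus missed the criterion narrowly. The NRF1 ratio rests on 34 central and 20 flank sites. For so rare a site the highest shuffle can also rest on few sites, so the criterion does not decide on NRF1. GATA sites, bound by factors of blood, endoderm and V2b interneurons (0.582), and HNF4 sites of hepatocytes (0.716) were sparser at the centre than in the flanks, the latter within counting error (0.502 to 1.02). Shuffles of these consensus sequences had median ratios of 0.538 and 0.977. No TP63 site was found in the central windows. The full NFI site did not meet the criterion in the conservative list, where its ratio was 4.33 (1.40 to 13.4; shuffles up to 5.77). That ratio rests on 6 central and 6 flank sites, too few to decide. SOX sites were enriched with wider windows (1.04) and in the conservative list (1.07), TAATTA (1.248) and PU.1 sites (1.42) with wider windows, and NFY sites in the conservative list (2.55) and in replicate 2 alone (1.86). At the 14555 promoter summits, RFX (12.5), ETS (10.1), CTCF (7.58), NFY (7.31), NRF1 (5.50), SP/KLF (3.68), PU.1 (2.38) and POU (1.86) sites were enriched, 8 of 30, and the E-boxes were not (1.38 and 0.694). The PU.1 ratio there rests on 21 central sites, at 0.144% of summits. Its consensus AGAGGAAGTG shares the letters GGAAGT with the ETS consensus ACCGGAAGT, so the PU.1 and ETS results are not independent.

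**Figure D5:**
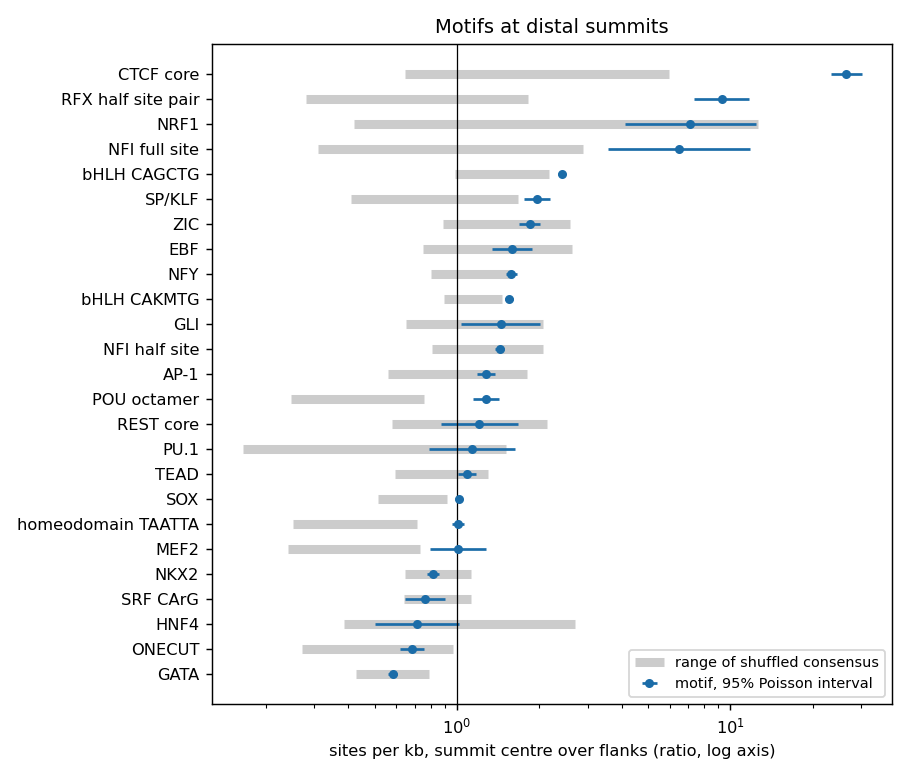
Ratio of site density at distal summit centres over flanks (horizontal log axis) for motifs with at least 20 central sites, as points with 95% Poisson intervals, and the range over shuffled consensus sequences as grey bars. CTCF (26.5) and RFX (9.28) lie far to the right of their shuffles.

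The distal regions of highest fold were called in both replicates, with mean folds of 22.1 to 51.2. The strongest lay between genes at X:143482936-143483180 (fold 51.2 ± 1.18) and 2:69355469-69355735 (49.1 ± 5.02), followed by 2:3964423-3964690 (39.0 ± 2.22), 5:60042765-60043151 (37.1 ± 1.22), 10:96077546-96077951 (36.4 ± 2.48, in an intron of a pseudogene), 12:97061368-97061856 (29.0 ± 0.123) and 6:9889881-9890225 (25.3 ± 0.755; SD, n = 2 throughout). The others lay in an exon of the mitochondrial leucyl-tRNA synthetase gene Lars2 at 9:123461727-123462252 (23.2 ± 0.0319), an intron of Cldn34d at X:76598493-76599189 (22.7 ± 2.20) and an intron of Nkain3 at 4:20191761-20192039 (22.1 ± 0.0706). Of these 10 regions, those on chromosomes 5, 10, 12 and 6 aligned to the mitochondrial genome over 86.6%, 86.7%, 74.6% and 89.9% of their length, at 95.5 to 99.7% identity. The region at 2:69355469-69355735 aligned to it over 48.3% of its length at 100% identity.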

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

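All tests on the regions left out of the thresholded lists were settled only after a first result had been seen. The ranked lists, which no comparison used, held peaks that met the global IDR threshold of 0.05 and were missing from the matching thresholded lists. Their number was 183 in replicate 1, 161 in replicate 2, 202 for the conservative list and 235 for the optimal list. Of the 202, 65 lay on scaffolds outside the assembled chromosomes, where the thresholded list had 0, and 137 lay on chromosomes and formed 53 regions. The largest −log10 p among them was 8367, at 1:24611586-24616165, a region of 4580 bp that matched the mitochondrial genome over 100% of its length at 99.96% identity. At 6:103648978-103649357 the fold was 41.5, and at 2:98666169-98667337 it was 10.53 with 80.3% of the bases marked as repeats.

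Nuclear copies of mitochondrial DNA account for 1 of the 53 regions (1.89%), which argues against them as the shared cause. Repeat sequence and a filter on position cannot be told apart from other causes. The median share of repeat-marked bases was 34.2%, between the 7.95% of conservative regions and the 50% set for repeats, with 18 of 53 regions mostly repeat-marked. A filter that removes given positions may leave no region there in any list, and 1 of 53 regions overlapped a region of another list, so a filter on position stays open. The regions were first chosen by the rounded IDR score, which gave 8 overlaps among 60 regions and would have counted against a filter on position. The exact IDR was adopted after that count was seen, because peaks with an IDR just above 0.05 can share the rounded score. The result on a filter depends on this choice. No biological explanation was tested, since the design has 1 group.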

How the results depend on the processing

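Alternatives were set beforehand, except that 3 choices were made after seeing the data, the matched contrast of neural and other lists, its wider neural group and the exact IDR, which replaced the rounded score once the count under the latter was seen. Left-out peaks numbered 202 by the exact IDR and 214 by the rounded score, and their overlapping regions 1 and 8. No paired analysis was possible because there was 1 group. With IDR lists the replicates had 25979 and 13742 regions, and unmerged peaks numbered 133238 and 74741. The shared parts of replicates 1 and 2 were 37.8% and 71.7% with reciprocal overlap, 43.5% and 97.48% at −log10 q of at least 5, 51.4% and 98.0% with IDR lists, and 74.9% and 79.5% with equal numbers. Regions of a single replicate numbered 9534 and 7768 with equal numbers, and 10734 in replicate 2 with reciprocal overlap. The Spearman correlation was 0.860 for −log10 p and 0.868 with reciprocal overlap. The promoter share was 50.3% in the conservative list, 42.4% in the optimal list and 20.7 to 36.4% without either replicate. The raw difference between neural and other lists in promoters was 51.8 points with a window of 500 bp and 47.6 to 54.3 without either replicate, against 41.9, 40.7 and 42.0 in genes matched on CpG, and 5.89 points of the main difference lay beyond matched genes. In distal regions it was 5.25 within 500 kb, 0.957 in the conservative list and 1.84 to 4.17 without either replicate, against 1.85, 0.229, 0.511 and 1.28 in matched genes. The conservative list held 9 regions in HoxA, 9 in HoxB, 8 in HoxC and 8 in HoxD, against 16 to 20 in HoxA, 10 to 20 in HoxC and 14 to 22 in HoxD without either replicate. Unmatched random lists turned the promoter percentiles of interneuron (89.7), forebrain and midbrain (53.2) and neural crest genes (58.6) from low to above the middle, as matching on CpG was dropped. The distal percentile fell from high to between 90.02 and 97.4 in at least 1 setting for the pan-neuronal, progenitor, dorsoventral, interneuron, forebrain and midbrain lists, and to the middle for Hox genes (50 in the conservative list, 50 to 100 without either replicate), muscle genes (49.5 in the conservative list) and housekeeping genes (49.99 in the conservative list, 39.8 to 49.5 without either replicate), where a median of whole counts can move by a full region; the cause was not tested. Moves were judged against the SD of the 2 replicates' own values, which differed widely between lists and between motifs. The replicates' own lists were also among the alternatives, so the values that set the SD were themselves judged against it. The counts within the SD are therefore not independent of it. Of 114 alternatives for promoter percentiles of lists, 46 lay within that SD of the main value. Of the others, 20 rose, 45 fell and 3 turned from low to above the middle as given above. For muscle genes 2.625 counted as within the SD of 49.97, and for pan-neuronal genes 99.9 counted as a rise from 99.4. Of 114 for distal regions, 62 lay within that SD of the main value, 13 rose, 33 fell and 6 fell from high to the middle or below. Counting lists that began neither high nor low as well, 27 promoter and 15 distal alternatives lay on the other side of the 50 percentile. Of 115 motif ratios, 59 lay within that SD of the main ratio, 28 rose and 28 fell, and the number of enriched motifs was 7 to 10. The lack of read totals limits every comparison of the number of regions between replicates.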

Other observations

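The comparison of fold by place, the sharing by rank and the density by chromosome were chosen only after the results were seen. The rules for the patterns weighed below were set before their results. The interval used for a missing cell type was not part of these rules. At ranks below the strongest, promoter regions of replicate 1 were found in replicate 2 more often than other regions. In decile 4 by −log10 p the shares were 81.7% (79.0 to 84.2%) and 58.6% (57.4 to 59.8%). Over all ranks, promoter regions of replicate 1 had a median width of 1074 bp, against 410 bp in introns and 424 bp between genes. Wide regions can meet an overlap of 1 bp more easily, and width was not taken into account. At the strongest pooled regions the median fold of replicate 2 over replicate 1 was 0.864 at 8089 promoters and 0.771 at 1557 distal regions. The X chromosome held 7.22 regions per Mb, against 19.2 to 27.6 on the autosomes.

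Replicate 1 had 1.90 times as many regions as replicate 2. At 9999 of the 10000 strongest pooled regions, called in both, the median ratio of fold was 0.853 and that of −log10 p was 0.369, replicate 2 over 1. The fold ratio lies between the 0.9 set for lower depth alone and the 0.8 set for lower enrichment, so a lower depth and a lower enrichment in replicate 2 cannot be told apart without read totals. A cell type missing from replicate 2 could lower the distal count of its genes. The rule set beforehand took lists with at least 10 distal regions in replicate 1 and a limit of 1 / 1.5 for the ratio. The lowest ratio was 0.692 for epithelial genes (9 against 13 regions), above that limit, so by the rule it counts against a missing cell type. The interval of 0.261 to 1.75, which was not part of the rule, reaches below the limit. Counts this small cannot decide the question. A difference between the pools of 17 and 34 embryos was not tested.

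The region at 12:97061368-97061856 had the highest −log10 p of the replicated list, 7475. It aligned to the mitochondrial genome over 74.6% of its length at 99.7% identity, and 4.70% of its bases were marked as repeats, which argues against repeat sequence. A candidate explanation is that reads of mitochondrial DNA were placed on this nuclear copy. Of the 10 distal regions of highest fold, 4 aligned to the mitochondrial genome over at least 50% of their length, 1 over 48.3%, just under that limit, and 5 not at all. Another match in the genome was found for 2, those on chromosomes 5 and 6, which were both among the 4 aligned to the mitochondrial genome. Outside these 4, no region had another match. Both counts lie between the 5 set for a shared cause and the 1 set against it. Either kind of copy stays open as the cause for the regions that have it, and the 2 counts are not separate. No biological explanation was tested.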
